A study of Homo sapiens with 56 samples.

How the data were processed

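The deposited values are counts of sequencing reads per guide RNA (knockout libraries) or per barcode (overexpression library), per the file headers. Per the labels' protocols, genomic DNA was extracted from HAP1 cells and guides or barcodes were amplified by PCR and sequenced. Per the submitters' processing notes, the tools were cutadapt 4.8 and MAGeCK 0.5.9.2.4 and the genome build was GRCh38.p13; the notes state no role or parameter for either tool. The labels describe the transporter knockout library as carrying unique molecular identifiers but state no collapsing of reads by them, so the counts were treated as PCR reads, and their counting error says nothing of molecules. Per the labels' protocols each replicate was seeded into its own dish after transduction and antibiotic selection. Separate transductions are not stated, so p-values measure the spread between these dishes, which may be technical. The labels give no sequencing batch.

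Each sample column was taken as raw counts and each was used (0 sample columns were left over). The genome-wide control is titled D in the labels while its columns are headed DMSO; it is called D here. The titles of the 9-day DAT551 samples spell the name with a further digit, while their treatment labels give DAT551, which was used. Counts were summed over the guides of a gene. The 60 non-cutting guides, the 10 empty barcodes and the 142 control guides of the genome-wide library were left out of the gene tests. In the transporter knockout library, 642 of 664 target names matched a current symbol of the reference gene table (assembly GRCh38.p14), 21 an older name and 1 none. In the overexpression library these were 437, 17 and 3 of 457, and in the genome-wide library 16700, 1317 and 36 of 18053. That table was used for names and, through its gene start positions, for the order of genes and how many lie between them. Its assembly is not the one in the notes, and positions of guides were not checked.

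The gene test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, robust fit, R 4.3.3) with TMM scaling, genes filtered at a minimum count of 10, only the groups compared in a fit, and Benjamini-Hochberg adjustment with a threshold of 0.05. Groups of other compounds were kept out because a strong selection was thought to widen the spread between dishes. The same test was run for each guide. A gene counted as backed by guides when at least 2 guides had an unadjusted p under 0.05 in its direction and the median guide moved that way. Levels in CPM use the library totals after TMM adjustment. Standard errors come from the libraries' log2 CPM with a prior count of 2. Differences of effects (9 against 3 days, with against without doxycycline) were tested as a contrast of 4 groups. Intervals of differences are 95% t intervals from the standard errors and take no account of replicate numbers.

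Gene lists were tested with fry (limma 3.58.1), which estimates the correlation between genes from the data, adjusted over the lists with at least 2 measured members. They were ABC multidrug exporters, MATE exporters, organic ion uptake transporters, essential transporters, amino acid transporters, zinc transporters, mitochondrial carriers, the SLC35 family with other nucleotide sugar transporters, the ABCA to ABCG families, V-ATPase, SLC9A exchangers, CRL4-CRBN, CRL2-VHL, neddylation and cullin exchange, the COP9 signalosome, the ubiquitin transfer enzymes of cullin ligases, the proteasome, apoptosis genes, anti-apoptotic genes and cytosolic ribosomal proteins. The library's own classes of essentiality controls, PROTAC controls and cutting negative controls were added as lists.

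The genes named were up to 12 highest and 12 lowest in log2 fold change among those past the threshold with guide support and no overlap between the libraries of both groups. In the overexpression library, with 1 barcode per target, guide support was not asked. Whatever their value, the ABC multidrug exporters were added for MZ1, DAT551 and SIM1, SLC35F2 for YM155, and CRBN, VHL and the lists of ligase, neddylation, COP9 and transfer enzymes for d9A-2, and a gene named for one compound could be given for others. Not every gene that the rule picked is given in the text. The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise.

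The alternatives were DESeq2 (1.42.0) in place of edgeR, no filter on low counts, all groups of a table in one fit, total counts in place of TMM, scaling on control guides (the 120 cutting negative-control guides of the transporter library, the control guides of the genome-wide library), the replicate number as a block, an alpha-RRA ranking over guides with 1e+06 random draws, and leaving out each library in turn. Leaving out the 3-day SIM1 replicate 3 together with the replicate block was added after the data were seen.

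Replicate numbers were taken to pair libraries where the deviations of same-numbered libraries from their group means correlated above 0.1 in every pair. This held for MZ1, DAT551 and SIM1 against DMSO at 3 days (lowest r 0.454, 0.344 and 0.107) and at 9 days (0.172, 0.225 and 0.146). It also held for MZ1 against DAT551 and against SIM1 at 3 days (0.510 and 0.114) and for the comparisons between MZ1, DAT551 and SIM1 at 9 days (0.567, 0.459 and 0.390). It did not hold for YM155 against DMSO, for the Input, for DAT551 against SIM1 at 3 days or for the genome-wide library. In the overexpression library it did not hold for MZ1 or YM155 against DMSO, with or without doxycycline, or for doxycycline alone in DMSO. That statement does not cover the pairing of the arms with and without doxycycline under the same compound. The labels name no shared day behind the numbers, so this pairing is read from the data alone.

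The test was run on simulated counts with 200 genes changed by known amounts, drawn from the real libraries' means and sizes. For MZ1 at 3 days it recovered 100% of genes changed by a log2 fold change of 0.5, 1 or 2 among 664 genes, with 1 false call among 464 unchanged ones. For MZ1 with doxycycline in the overexpression library it recovered 59.7%, 100% and 100%, with 8 false calls of 257. For d9A-2 among 18053 genes it recovered 1.49%, 34.3% and 97.0%, with 3 false calls of 17853, so changes of less than 2 were often not detectable. Effects shared between comparisons with the same controls were set against 100 simulations of unchanged groups.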

Results

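The series measured how knocking out or overexpressing transporter genes changed the growth of HAP1 cells, a near-haploid human leukaemia-derived cell line, under protein degraders and other compounds. Cells carried a pool of lentiviral constructs, genomic DNA was taken after treatment, and the deposited values are the sequencing counts of each guide RNA or barcode. Counts are compared with a control group. A guide or barcode that gains counts marks cells that grew more or were lost less than in the control. One that loses counts marks cells that grew less or were lost more. The 56 libraries came from 4 screens. A transporter knockout library of 4043 guides against 664 targets was read after 3 days in 14 libraries (3 each of DMSO, MZ1, DAT551 and SIM1, and 2 of the Input) and after 9 days in 15 libraries (3 each of DMSO, MZ1, DAT551, SIM1 and YM155). A transporter overexpression library of 457 targets and 10 empty controls was read in 18 libraries (3 each of DMSO, MZ1 and YM155, with and without doxycycline, which switches the cDNA on). A genome-wide knockout library of 71090 guides against 18053 genes was read in 9 libraries (3 each of d9A-2, its control titled D, and Input).

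MZ1 joins a ligand of the BET bromodomain proteins to a ligand of the VHL ubiquitin ligase, and SIM1 is a trivalent BET degrader that also recruits VHL. YM155 is a survivin-suppressing compound that enters cells through SLC35F2. DAT551 and d9A-2 are known here only by their code names. Doses differed between compounds and between times. At 3 days they were 100 nM MZ1, 245 nM DAT551 and 5.3 nM SIM1, and at 9 days 180 nM MZ1, 500 nM DAT551, 3.15 nM SIM1 and 18 nM YM155. The overexpression screen used 180 nM MZ1 or 20 nM YM155 for 8 days with or without 1 µg/ml doxycycline, and the genome-wide screen used 250 nM d9A-2 for 2 days.

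Total counts per library ran from 11940539 to 15637873 in the 3-day knockout screen, from 13866733 to 16826186 in the 9-day screen, from 331094 to 765704 in the overexpression screen and from 19886773 to 81735476 in the genome-wide screen. The median count per guide or barcode was 3362, 3243, 742 and 360 in that order, and 0.0141%, 0.0528%, 1.38% and 1.497% of the values were 0. Replicates spread far beyond counting error: the chi-square per guide or barcode between a pair of replicates ran from 14.3 to 393, from 26.5 to 457, from 6.34 to 34.6 and from 12.8 to 154. Levels are in CPM, counts scaled to the library's total after TMM adjustment, while shares in % are of the plain total. Values given below as a number ± a number are log2 fold changes ± standard error between libraries, with n = 3 libraries in each group unless stated. Gene calls rest on an edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the genes of a comparison. In the knockout screens the text names genes that passed it with several guides and whose treated libraries all lay on one side of all control libraries. It names any others as such. Each target of the overexpression library had 1 barcode, so its calls rest on single constructs and no such backing could be asked.

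Culture without drug showed first whether the knockouts acted. From the Input (n = 2) to DMSO at 3 days, guides against 20 of the 20 essential genes that the library holds as controls fell, with no rise (fry, adjusted p = 3.66e-05; 20 of 20 also adjusted over the list alone). POLR2L, a subunit of RNA polymerases, fell by 4.58 ± 0.09 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.97e-06). The ribosomal protein genes RPS19 and RPL15 stood at −4.49 and −4.46, and the splicing gene SNRPD1 at −4.45. Among 22 essential transporters 19 fell and 1 rose (fry, adjusted p = 1.35e-05), with ATP2A2, the calcium pump of the endoplasmic reticulum, at −4.03. All 6 cytosolic ribosomal protein genes in this library fell (fry, adjusted p = 9.43e-05), as did both of its proteasome genes (fry, adjusted p = 0.000121). ABCB6, a porphyrin transporter, rose by 1.15 ± 0.17 and the zinc exporter gene SLC30A1 by 0.71, though an alpha-RRA ranking over guides did not call the latter (adjusted p 1.04e-94 to 0.578 over its alternatives, the last in that ranking). In all, 153 of 664 genes rose and 171 fell. Scaled on the 120 cutting negative-control guides, 98 rose and 228 fell and the median of all genes moved to −0.12. This scaling centres those guides, so the direction of their own genes under it decides nothing. The 20 genes behind those control guides showed 4 rises and 5 falls, with an upward fry result (adjusted p = 0.0111) that turned downward under that scaling (adjusted p = 0.0088) and was lost without any single library (adjusted p = 0.289 without Input replicate 1, 0.0995 without Input replicate 2, and 0.0626, 0.0721 and 0.0509 without DMSO replicates 1, 2 and 3). The count of calls was 557 and 537 without Input replicates 1 and 2, and 191, 174 and 178 without DMSO replicates 1, 2 and 3.

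The comparison of MZ1 with DMSO asks which transporter losses make cells more or less sensitive to this degrader. At 3 days the strongest loss was of ABCC1, the drug exporter also called multidrug resistance-associated protein 1, at −3.82 ± 0.17 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.09e-06). Its level fell from 1645 ± 49.7 to 117 ± 25.3 CPM (SD, n = 3), and all 6 guides fell, with log2 fold changes from −5.16 to −3.02. SLC7A11, the cystine importer that feeds glutathione synthesis, fell (−0.79 ± 0.05), as did SLC3A2, its heavy-chain partner (−0.42 ± 0.03). SLC35A2, the Golgi importer of UDP-galactose, fell (−0.70 ± 0.04) and so did SLC30A9, a zinc transporter (−0.79 ± 0.10). UBE2M, the enzyme that attaches NEDD8 to cullins, rose most, by 1.25 ± 0.07 with 5 of 6 guides rising. Its guides held 693 CPM in the Input (n = 2), 92.5 in DMSO and 219 in MZ1, so they were lost less than in DMSO. The proteasome ubiquitin receptor PSMD4 rose by 1.05 ± 0.17, the COP9 signalosome subunit COPS8 by 0.88 ± 0.14, the ubiquitin-conjugating enzyme UBE2G1 by 0.37 ± 0.04 and the organic anion transporter SLCO1A2 by 0.30 ± 0.05. In all, 28 of 664 genes rose and 20 fell, and guides backed 22 and 20 of them.

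Of the 14 ABC multidrug exporters, ABCC1 and ABCC6 (−0.20 ± 0.04) fell under MZ1 at 3 days, and the other 12 lay between −0.07 and 0.08. The list as a whole fell (fry, adjusted p = 0.000119), with a mean of −0.30 that ABCC1 carried and a median of −0.02; 2 fell adjusted over the list alone. ABCB1, the P-glycoprotein gene, stood at −0.07 ± 0.01. Of the 6 genes that the library holds as PROTAC controls (COPS8, CRBN, GPS1, PSMD4, UBE2G1 and UBE2M) 4 rose, 5 adjusted over the list alone (fry, adjusted p = 0.000794), and CRBN stood at −0.11 ± 0.05. Of 31 genes of the SLC35 family of nucleotide sugar transporters 2 fell (fry, adjusted p = 0.00627, and 0.0833 when scaled on control guides). Of 48 mitochondrial carriers 3 rose and 6 fell (fry, adjusted p = 0.0222). That last call was lost under control-guide scaling (0.420), with the replicate number as a block (0.0529), and without DMSO replicate 2 (0.0779) or 3 (0.0851) or MZ1 replicate 1 (0.0699) or 3 (0.0739). Of 18 amino acid transporters 1 rose and 2 fell (fry, adjusted p = 0.195), and none of the 9 SLC9A sodium-proton exchangers passed (fry, adjusted p = 0.494). The fry test asks whether a list moves one way on balance and does not compare it with other genes.

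Replicate numbers paired the libraries of this comparison, and 99 genes passed with the replicate number as a block. That fit also called ABCB1 (adjusted p = 0.0266), ABCB4 (0.00867) and ABCB5 (0.00144), with estimates from −0.07 to 0.08 and adjusted p values up to 1 over their alternatives; ABCB5 was also called without MZ1 replicate 3 (0.0495). It lost the call of the proteasome list, in which 1 of 2 genes rose (fry, adjusted p = 0.00707, and 0.0655 with the block). A fit of all 5 groups of the table called 6 genes, and among the named ones ABCC1, UBE2M, SLC7A11, SLC35A2, SLC3A2 and SLCO1A2 kept their calls in it. Of 25 named genes that passed, 22 kept their call with each library left out in turn.

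DAT551 against DMSO asks the same question for a second compound, here at 245 nM and 3 days. ABCC1 fell (−4.02 ± 0.22; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000377). SLC35A2 fell (−0.56 ± 0.06), as did SLC30A9 (−0.50 ± 0.08), SLC7A11 (−0.49 ± 0.02), ABCC6 (−0.26 ± 0.05) and SLC3A2 (−0.27). UBE2M rose by 0.83 ± 0.09, COPS8 by 0.59 and UBE2G1 by 0.32. PSMD4 rose by 0.70 ± 0.18, a call lost without DAT551 replicate 2 (adjusted p = 0.0620) and in the alpha-RRA ranking (0.0582). In all, 17 of 664 genes rose and 14 fell, with 74 calls under the replicate block. A fit of all 5 groups called 5, among the genes named here ABCC1, SLC35A2, SLC7A11 and SLC3A2, and DESeq2 called 52. The 14 ABC multidrug exporters fell as a list (fry, adjusted p = 0.00450) with a mean of −0.30 and a median of 0.00, and 2 of them fell, also adjusted over the list alone; without DMSO replicate 3 the list's adjusted p was 0.0537. The PROTAC controls rose as a list with 4 of 6 rising (fry, adjusted p = 0.00450, and 0.0512 without DMSO replicate 3).

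SIM1 against DMSO at 5.3 nM and 3 days gave 5 rises and 4 falls, all of which the guides backed. SLC7A11 fell (−0.80 ± 0.06; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000894), as did SLC3A2 (−0.52 ± 0.06), and SLC7A8, an amino acid transporter, rose by 0.39 ± 0.02. SLC9B1P3, an SLC9 pseudogene, rose by 0.86 ± 0.04. UBE2M rose by 2.10 ± 0.22 (adjusted p = 0.0236), a call lost under the replicate block (0.0970) and without DMSO replicate 1 (0.186), 2 (0.183) or 3 (0.168) or SIM1 replicate 1 (0.116) or 2 (0.153). The calls of SLC9B1P3 (0.0530) and SLC3A2 (0.0565) were lost without DMSO replicate 3. ABCC1 stood at −1.70 ± 1.03 and did not pass (adjusted p = 0.591), and its libraries spread widely. In SIM1 replicate 3 ABCC1 held 1232 CPM against 132 and 161 in replicates 1 and 2. Without that library ABCC1 fell (−3.49) and 73 genes passed (47 up, 26 down).

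**Figure D1:**
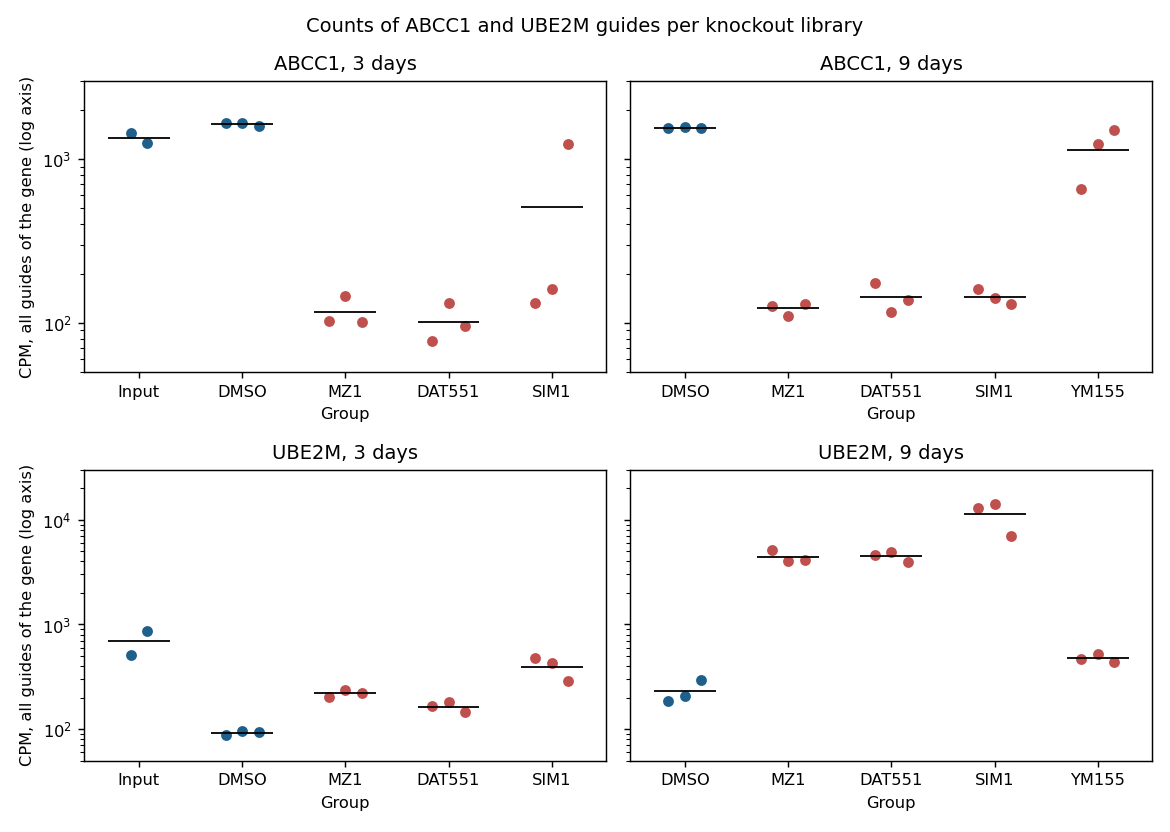
CPM (log axis) of all guides against ABCC1 and UBE2M in each library of the transporter knockout screens, by group at 3 and 9 days; points are libraries and lines are group means. ABCC1 stood at 1645 in DMSO and 117 in MZ1 at 3 days, and 1 SIM1 library stood at 1232.

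That library stood apart across whole classes of guides. ABC guides took 9.01% of its counts against 6.44% to 6.63% in the other 11 cultured libraries at 3 days, and P-type ATPase guides 6.13% against 4.23% to 4.37%. Guides against the essential control genes took 0.736% against 0.343% to 0.374%, where the Input held 3.29% to 3.33%. Counts of calls for SIM1 at 3 days were 4, 4 and 2 without DMSO replicates 1, 2 and 3 and 4 without SIM1 replicate 2. With replicate 3 left out and the replicate block added, an alternative chosen after the data were seen, 93 genes passed and ABCC1 stood at −3.52. Scaled on control guides 12 genes rose and 4 fell. None of the 14 ABC multidrug exporters passed (fry, adjusted p = 0.751, pointing up); without replicate 3 the list fell (0.0105). Of the 6 PROTAC controls 1 rose, 3 adjusted over the list alone (fry, adjusted p = 0.105).

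**Figure D2:**
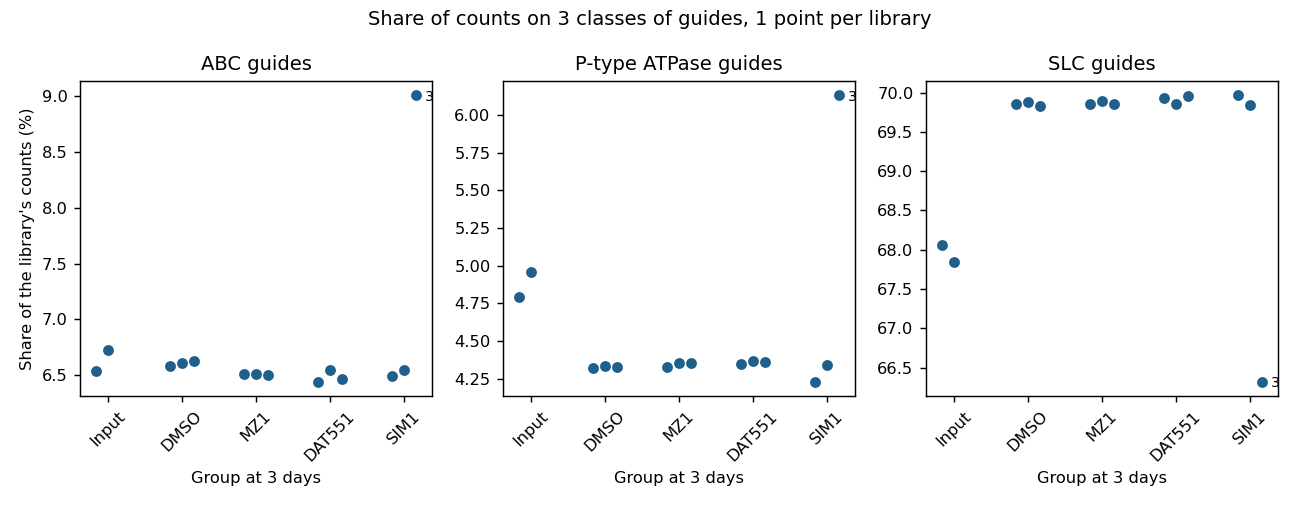
Share of each library's counts (%) on ABC, P-type ATPase and SLC guides in the 3-day knockout screen, 1 point per library, by group; the axes do not start at 0. SIM1 replicate 3, marked 3, held 9.01% ABC guides against 6.44% to 6.63% in the other 11 cultured libraries.

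At 9 days MZ1 (180 nM) left the same exporter lowest. ABCC1 fell (−3.66 ± 0.08; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.95e-11). SLC25A22, a mitochondrial glutamate carrier, fell (−0.75 ± 0.02), as did SLC35A2 (−0.65 ± 0.07). UBE2M rose by 4.26 ± 0.23, from 230 to 4413 CPM, COPS8 by 2.65 ± 0.17 and PSMD4 by 2.14 ± 0.18. GPS1, another COP9 subunit, rose by 1.33 ± 0.09 with 2 of 6 guides, and the alpha-RRA ranking did not call it (adjusted p 7.35e-12 to 0.939 over its alternatives). ATP1B3, a beta subunit of the sodium pump, rose by 0.82 and SLC30A1 by 0.86. SLC9B1P3 rose by 2.71 ± 0.08 and SLC39A12 by 0.68 ± 0.06; they are the nearest library genes on either side of CUL2, the cullin of the VHL ligase, with 10 and 60 protein-coding genes between. ABCC6 rose by 0.28 ± 0.04, a call that the alpha-RRA ranking (0.668), the fit of all groups (0.997) and the data without DMSO replicate 2 (0.0637) or 3 (0.0685) did not give. In all, 28 of 664 genes rose and 19 fell (37 and 15 scaled on control guides), and a fit of all 5 groups called 23. The ABC multidrug exporters fell as a list, with 1 rise and 1 fall of 14 also adjusted over the list alone (fry, adjusted p = 0.000892), a mean of −0.24 and a median of 0.01. The 41 genes of the ABCA to ABCG families held 2 rises and 1 fall (fry, downward, adjusted p = 0.00425, with 0.142 under control-guide scaling and 0.0575 under the replicate block). The PROTAC controls rose with 5 of 6 (fry, adjusted p = 0.000117), and both COP9 genes rose (fry, adjusted p = 0.000333).

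DAT551 at 500 nM and 9 days gave 37 rises and 24 falls. ABCC1 fell (−3.45 ± 0.17; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.53e-10), as did ATP8B2, a P4-ATPase (−0.84 ± 0.05). UBE2M rose by 4.29 ± 0.23, COPS8 by 2.87 ± 0.09, SLC9B1P3 by 2.36 ± 0.11 and PSMD4 by 2.00 ± 0.21. ATP1B3 rose by 1.04. SLC6A11, a transporter of the neurotransmitter GABA, rose by 0.83 ± 0.05, though a fit of all groups did not call it (adjusted p 2.11e-69 to 0.0603 over its alternatives). It is a neighbour of VHL in gene order, as is ATP2B2. ABCC6 rose by 0.70 ± 0.07, which the alpha-RRA ranking did not call (adjusted p 1.62e-24 to 0.0640 over its alternatives). Of 24 zinc transporters 3 rose and 1 fell (fry, upward, adjusted p = 0.00910, and 0.0509 with the replicate block). The PROTAC controls rose with 5 of 6, 5 up and 1 down adjusted over the list alone (fry, adjusted p = 0.000167). The ABC multidrug exporters held 1 rise and 1 fall and did not pass as a list (fry, adjusted p = 0.0536). Scaled on control guides 40 genes rose and 10 fell. DESeq2 called 92, the alpha-RRA ranking 38, a fit of all 5 groups 20, and the count without DMSO replicate 2 was 38.

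SIM1 at 3.15 nM and 9 days gave 26 rises and 8 falls, all backed by guides. ABCC1 fell (−3.43 ± 0.09; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.99e-09), as did SLC7A11 (−0.87 ± 0.12) and SLC3A2 (−0.86 ± 0.08). UBE2M rose by 5.63 ± 0.39, from 230 to 11396 CPM. SLC9B1P3 rose by 2.78 ± 0.15, PSMD4 by 2.75 ± 0.31, COPS8 by 1.62 ± 0.12 and ATP13A1, an endoplasmic reticulum P5-ATPase, by 1.57 ± 0.13. MPDU1, needed to use mannose-phosphate dolichol in glycan assembly, rose by 2.48 ± 0.15, and SLC35A1, the Golgi importer of CMP-sialic acid, by 0.94 ± 0.03. ABCC6 stood at 0.45 ± 0.11 (adjusted p = 0.0214, a call lost without DMSO replicate 1 (0.0848), 2 (0.0777) or 3 (0.0942), in the fit of all groups (0.232) and in the alpha-RRA ranking (0.170)). The PROTAC controls rose with 4 of 6 (fry, adjusted p = 0.000989). The ABC multidrug exporters fell as a list with 1 rise and 1 fall (fry, adjusted p = 0.0362), which the replicate block (0.0963), control-guide scaling (0.104) and the data without DMSO replicate 1 (0.125), 2 (0.0921) or 3 (0.126) or SIM1 replicate 2 (0.0731) did not give. A fit of all 5 groups called 19.

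**Figure D3:**
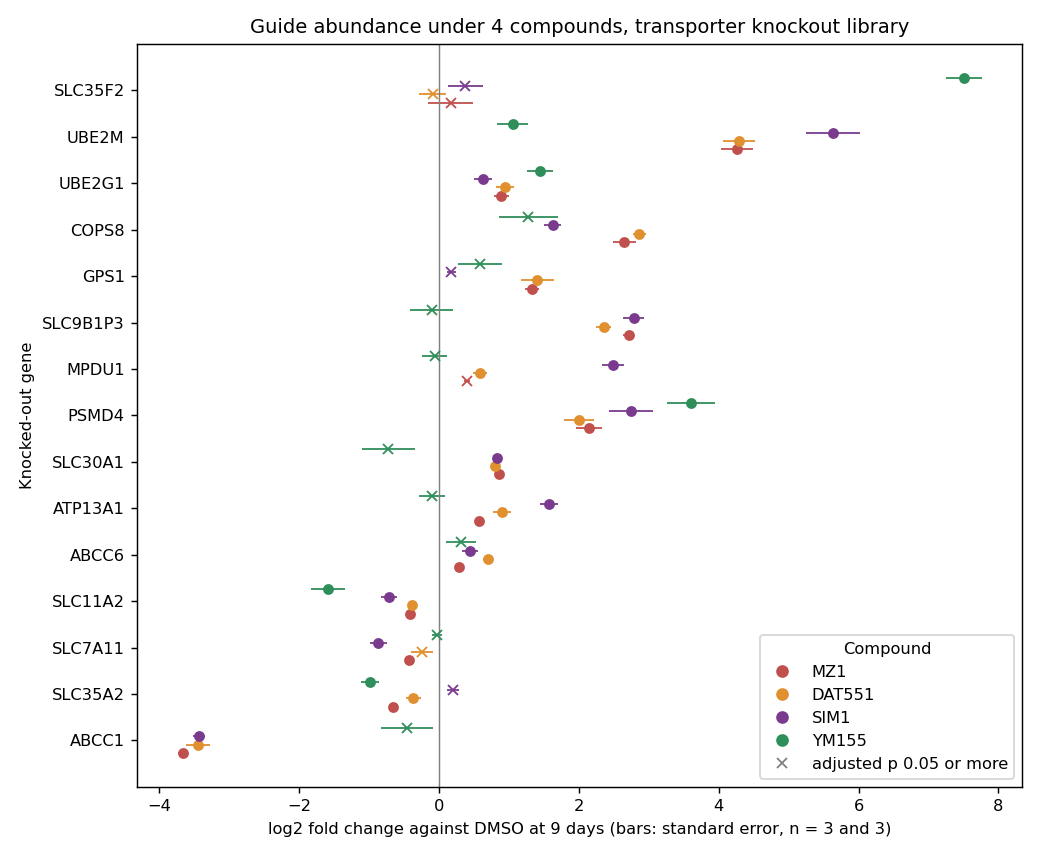
log2 fold change against DMSO at 9 days for 15 knocked-out genes under MZ1, DAT551, SIM1 and YM155; points are estimates, bars standard errors (3 libraries per group), and crosses mark an adjusted p of 0.05 or more. ABCC1 lay between −3.66 and −3.43 under the first 3 compounds, and SLC35F2 stood at 7.51 under YM155.

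YM155 at 18 nM served as a compound with a known importer. SLC35F2 rose by 7.51 ± 0.26 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.29e-05), and its guides took 41.5% ± 5.51 of the counts against 0.435% ± 0.0781 in DMSO (SD, n = 3). The mitochondrial pyruvate carrier genes MPC1 and MPC2 rose by 3.22 ± 0.21 and 2.78 ± 0.24, PSMD4 by 3.60 ± 0.35, SLC25A39, a mitochondrial glutathione importer, by 2.46 and SLC25A51, a mitochondrial NAD carrier, by 2.40. SLC11A2, an iron importer, fell (−1.59 ± 0.24), as did the lactate transporter gene SLC16A1 (−1.40 ± 0.07) and SLC25A28, a mitochondrial iron carrier (−1.30). ABCC1 stood at 1132 ± 438 CPM (SD) and did not pass. The PROTAC controls passed as a list under this compound too (fry, adjusted p = 0.0150, and 0.0076 to 0.106 over its alternatives). Besides PSMD4, UBE2G1 rose (edgeR quasi-likelihood test, adjusted p = 0.00177). UBE2M stood at 476 ± 45.9 CPM against 230 ± 59.4 in DMSO (SD). In all, 23 of 664 genes rose and 9 fell. Because SLC35F2 took so many counts, total-count scaling moved the median of all genes to −0.87 and gave 11 rises and 593 falls; control-guide scaling moved it to 0.22 and gave 33 rises and 5 falls. Mitochondrial carriers held 4 rises and 5 falls of 48 and pointed up (fry, adjusted p = 0.00696), but pointed down under total-count scaling (0.00105) and without YM155 replicate 1 (0.394). A fit of all 5 groups called 76 and DESeq2 53. The count was 18, 17 and 19 without DMSO replicates 1, 2 and 3, and 57 and 60 without YM155 replicates 2 and 3.

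Comparisons between compounds at one time set different doses against each other, so their differences join compound and dose. ABCC1 did not differ detectably between MZ1 and DAT551 at 3 days (0.20 ± 0.28, 95% interval −0.58 to 0.98) or at 9 days (−0.22 ± 0.18, −0.72 to 0.29). These intervals do not use the pairing by replicate number. Pair by pair ABCC1 was higher under MZ1 at 3 days (102, 146 and 102 against 77.8, 132 and 95.7 CPM). At 9 days it was lower in each pair (127, 111 and 131 against 174, 117 and 139 CPM). No alternative called it (lowest adjusted p 0.206 and 0.796 over the alternatives to the edgeR test). At 9 days the difference was −0.23 ± 0.11 between MZ1 and SIM1 (−0.54 to 0.08) and −0.01 ± 0.19 between DAT551 and SIM1 (−0.54 to 0.51). MPDU1 at 9 days was lower under MZ1 than under SIM1 (−2.09 ± 0.16; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.9e-06) and also under DAT551 (−1.90 ± 0.18), as was SLC35A1 (−0.76 and −0.50). COPS8 was higher under MZ1 and DAT551 than under SIM1, by 1.03 ± 0.18 and 1.24, and ATP1B3 by 0.76 and 0.99. UBE2M was lower under MZ1 than under SIM1 (−1.37 ± 0.34; adjusted p = 0.0409), a call lost without MZ1 replicate 1 (0.156), 2 (0.334) or 3 (0.361) or SIM1 replicate 1 (0.2001) or 2 (0.104). SLCO1A2 was higher under MZ1 than under DAT551 at 3 days (0.25 ± 0.05) and at 9 days (0.54 ± 0.09).

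At 9 days 3 genes were higher and 3 lower under MZ1 than under DAT551 (20 calls with the replicate block, and 3 without MZ1 replicate 2 or 3 or DAT551 replicate 2), 7 and 8 under MZ1 than under SIM1 (33 with the block), and 12 and 10 under DAT551 than under SIM1 (56 with the block, and 14 without DAT551 replicate 1 or 2). At 3 days the counts were 2 and 5 for MZ1 against DAT551, with 25 under the block and 4, 3, 4 and 3 without MZ1 replicates 1 and 2 and DAT551 replicates 1 and 3. SLC7A11 was lower under MZ1 there (−0.30 ± 0.05). For MZ1 against SIM1 at 3 days 4 genes were lower and none higher by edgeR (41 genes at an unadjusted p under 0.05, and 23 calls by DESeq2). SLC35A2 was among them at −0.91 ± 0.05 (adjusted p = 0.00296), but edgeR with the replicate block called 0 genes, with 42 at an unadjusted p under 0.05 (adjusted p 4.85e-53 to 0.0618 for SLC35A2 over its alternatives). Counts there were 2 without MZ1 replicate 1, 2 or 3 or SIM1 replicate 1, and 39 without SIM1 replicate 3. For DAT551 against SIM1 at 3 days 1 gene was higher and 3 lower. Without SIM1 replicate 3 that count was 43, and without SIM1 replicate 2 or DAT551 replicate 1, 2 or 3 it was 0 by edgeR (50, 29, 30 and 29 genes at an unadjusted p under 0.05, and 46, 23, 30 and 27 calls by DESeq2). ABCC1 did not differ detectably between MZ1 and SIM1 at 3 days (−2.12 ± 1.04, 95% interval −5.02 to 0.78, adjusted p = 0.740, and −0.33 without SIM1 replicate 3). Between DAT551 and SIM1 at 3 days it stood at −2.32 ± 1.05 (−5.24 to 0.60, adjusted p = 0.666, and 0.00251 to 0.908 over its alternatives). It passed at −0.52 without SIM1 replicate 3 and with the replicate block, an alternative chosen after the data were seen, but did not without that library alone (0.131).

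The compounds' effects were set beside each other across genes. At 9 days 25 genes rose under both MZ1 and DAT551, where independent lists would share 1.56, and 13 fell under both (0.687). For MZ1 and SIM1 these were 18 (1.096) and 7 (0.229), and for DAT551 and SIM1 20 (1.45) and 5 (0.289). Across the 664 genes, which are not independent replicates, the log2 fold changes of MZ1 and DAT551 at 9 days had r = 0.959 and a covariance of 0.101, against 0.4996 and 0.0117 in 100 simulations of unchanged groups. MZ1 and SIM1 had r = 0.873 with a covariance of 0.102 (simulated 0.0117). MZ1 and YM155 had r = 0.205 with 0.0342 (simulated 0.498 and 0.0116). At 3 days MZ1 and DAT551 had r = 0.960 with 0.0324 (simulated 0.484 and 0.00548), with 14 shared rises (0.717) and 13 shared falls (0.422). With SIM1 replicate 3 included, MZ1 and SIM1 had r = 0.562 there with 0.0274 (simulated 0.495, at most 0.736, and 0.00565), and DAT551 and SIM1 had r = 0.475 with 0.0218 (simulated 0.499 and 0.00565). Part of the excess may come from the shared controls, since 3 DMSO libraries could not be split into groups of 2.

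The change of each compound's effect from 3 to 9 days joins time with dose, since both differed. UBE2M rose further by 3.01 ± 0.24 under MZ1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.61e-06), by 3.46 ± 0.24 under DAT551 and by 3.54 ± 0.45 under SIM1 (adjusted p = 0.000162, and 0.0942 without the 3-day SIM1 replicate 3 under the replicate block). SLC9B1P3 rose further by 2.28, 2.12 and 1.93, and COPS8 by 1.78 under MZ1 and 2.27 under DAT551. SLC25A22 fell further (−0.71, −0.74 and −0.65). ABCC6 changed from lower to higher than DMSO, by 0.48 ± 0.05 under MZ1 and 0.96 ± 0.09 under DAT551. ABCC1 did not pass, at 0.16 ± 0.19 under MZ1 (95% interval −0.28 to 0.59; its call was reached without the 3-day MZ1 replicate 2, 0.0311) and 0.57 ± 0.28 under DAT551 (−0.07 to 1.22; 0.00951 without the 3-day DAT551 replicate 2). Under SIM1 ABCC1 pointed the other way and did not pass, at −1.73 ± 1.03 (−4.10 to 0.65, adjusted p = 0.681). Its estimate ran from −2.18 to 0.09 over its alternatives. The counts were 28 higher and 10 lower for MZ1, 26 and 11 for DAT551, and 10 and 2 for SIM1. The last was 22 without the 3-day SIM1 replicate 3 and 19 without the 9-day SIM1 replicate 3.

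The overexpression screen asks the converse question, which transporters protect or sensitise when switched on. Under MZ1 with doxycycline, the barcode of ABCC1 rose by 3.51 ± 0.51 and that of ABCB1 by 3.39 ± 0.15 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.15e-07 and 8.92e-09). Without doxycycline they stood at 0.07 ± 0.22 and 0.14 ± 0.89, and the difference between the arms passed at 3.54 ± 0.57 and 3.35 ± 0.89. SLC66A5 and SLC66A1 rose by 1.70 and 1.68, and TUSC3, a subunit of oligosaccharyltransferase, by 1.55. GFP, a control that transports nothing, rose by 1.61 ± 0.14. SLC1A4 and SLC1A5, exchangers of neutral amino acids, fell (−2.03 ± 0.30 and −1.71 ± 0.15), as did the sphingosine-1-phosphate exporter gene SPNS2 (−1.75 ± 0.13) and NIPA1, a magnesium transporter (−1.57 ± 0.13). In all, 116 of 449 cDNAs rose and 104 fell with doxycycline. Both measured ABC multidrug exporters rose (fry, adjusted p = 0.000269). Of 9 SLC9A exchangers 2 rose (fry, adjusted p = 0.0233), a list call lost without DMSO replicate 1 (0.111) or 2 (0.0789) or MZ1 replicate 1 (0.110), 2 (0.0525) or 3 (0.0806). Of 47 mitochondrial carriers 9 rose and 12 fell (fry, adjusted p = 0.237). The effect differed between the doxycycline arms for 154 of 451 cDNAs, 92 up and 62 down.

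Without doxycycline 6 of 450 cDNAs rose and 9 fell under MZ1. SLC51B, a subunit of a bile acid and steroid transporter, was among them at −0.64 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.73e-05). It also fell under YM155 without doxycycline, against the same DMSO libraries (edgeR quasi-likelihood test, adjusted p = 0.00159, highest 0.0578 over its alternatives). Its fall is thus not particular to MZ1. The count of calls under MZ1 was 6, 2 and 7 without DMSO replicates 1, 2 and 3, and 2 without MZ1 replicate 1. DESeq2 called 41, and a fit of all 6 groups 2.

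Under YM155 with doxycycline SLC47A1, the MATE1 exporter of organic cations, rose by 4.35 ± 0.19 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.23e-13), ABCB1 by 3.31 ± 0.15, and the organic cation transporter SLC22A2 by 3.04 ± 0.04. SLC35B2, the Golgi importer of the sulfate donor PAPS, rose by 2.45 ± 0.08. SLC35F2 fell (−3.48 ± 0.31). Without doxycycline it stood at −0.56 ± 0.05 and did not pass (edgeR quasi-likelihood test, adjusted p = 0.0763), and the difference between the arms passed at −2.87 ± 0.31. SLC11A2 fell (−1.59 ± 0.14), as did SLC25A39 (−1.42 ± 0.22). ABCC1 stood at 0.27 ± 0.52 and did not pass. Of 24 zinc transporters 1 rose and 9 fell (fry, adjusted p = 0.000488), among them SLC39A10, SLC39A14, SLC39A8 and SLC39A5 at −1.49, −1.21, −1.13 and −1.11. Of 23 organic ion uptake transporters 5 rose and 1 fell, 6 and 2 adjusted over the list alone (fry, upward, adjusted p = 0.00067), with a mean of 0.22 and a median of −0.08. The MATE list rose with 1 of its 2 members, both of them adjusted over the list alone (fry, adjusted p = 0.000488). In all, 51 of 450 cDNAs rose and 51 fell; total-count scaling gave 36 and 90 and moved the median to −0.14. The effect differed between the arms for 73 of 452 cDNAs, 43 up and 30 down.

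Without doxycycline 7 cDNAs rose and 9 fell under YM155 (4 and 13 under total-count scaling), SPNS2 among them at 1.02. That count was 3, 1 and 0 without DMSO replicates 1, 2 and 3 (for the 0 by edgeR, 70 at an unadjusted p under 0.05 and 12 calls by DESeq2) and 38 without YM155 replicate 3, and DESeq2 called 28. SPNS2 was not called without any DMSO replicate (0.149, 0.0590 and 0.0891 in order of number) or YM155 replicate 1 (0.0527). With doxycycline, 12 cDNAs rose under both MZ1 and YM155 where independent lists would share 13.2, and 25 fell under both (11.8). Both effects share their DMSO libraries, and unchanged groups simulated with shared controls gave 0 shared rises and 0.01 shared falls. Across cDNAs r was 0.245 against a simulated 0.493, but effects of 1 compound alone lower r, so these 2 values are not alike. The covariance was 0.104 against a simulated 0.0281.

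**Figure D4:**
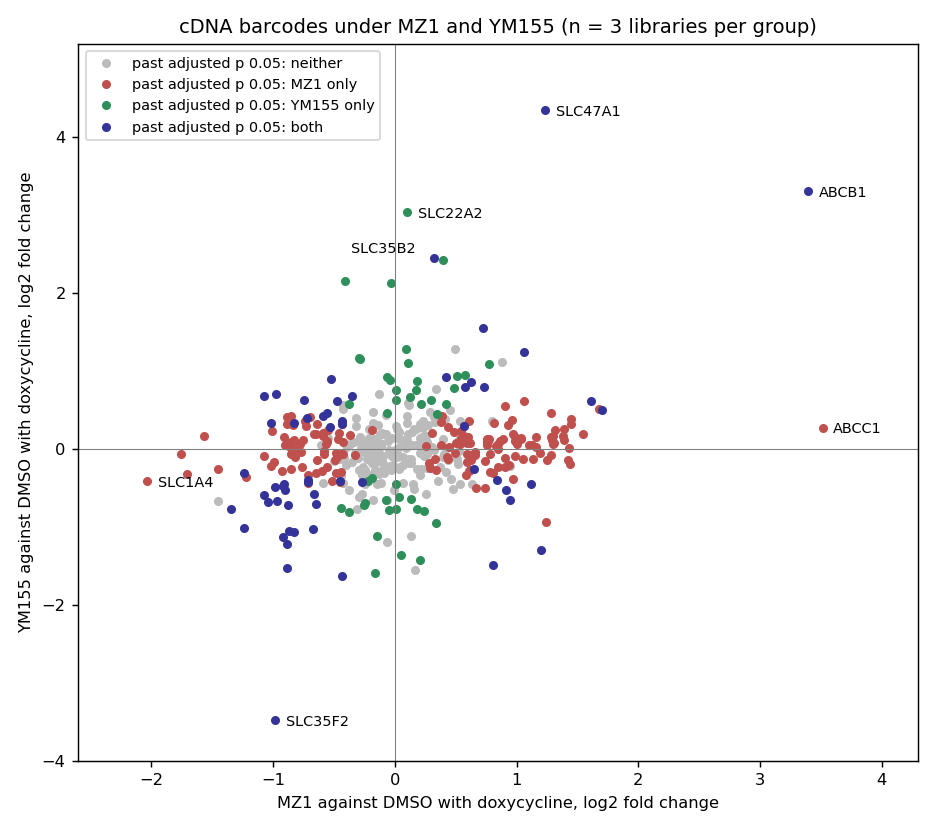
log2 fold change of each cDNA's barcode under MZ1 (x axis) and YM155 (y axis) against the same DMSO libraries, with doxycycline, 3 libraries per group. Each point is a cDNA, coloured by which of the tests it passed. ABCB1 rose under both compounds (3.39 and 3.31), ABCC1 under MZ1 (3.51) and SLC47A1 most under YM155 (4.35).

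Doxycycline itself changed the pool in DMSO, with 65 of 449 cDNAs rising and 90 falling (101 and 83 under total-count scaling, and 95 calls in a fit of all groups). The mitochondrial carrier SLC25A41 fell (−2.68 ± 0.07; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.32e-17), as did SLC25A37, a mitochondrial iron importer (−2.57). The iron exporter gene SLC40A1 fell (−2.08), as did MLKL_S358D, a form of a necroptosis effector that kills cells (−1.95 ± 0.26). NIPA1 rose by 1.18 ± 0.12 and SLC1A5 by 0.77, and both fell under MZ1 with doxycycline. The 2 comparisons use the same DMSO libraries with doxycycline, on opposite sides. A cDNA picked for high counts in those libraries is thereby pushed toward a fall under MZ1. Of 47 mitochondrial carriers 6 rose and 20 fell with doxycycline in DMSO, 8 and 20 adjusted over the list alone (fry, adjusted p = 2.5e-05).

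The genome-wide screen asks which genes d9A-2 needs to act. CRBN, the substrate receptor of the CRL4-CRBN ubiquitin ligase, rose most among the named genes, by 5.40 ± 0.23 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.63e-07), from 197 ± 49.9 to 8276 ± 1128 CPM (SD, n = 3). UBE2M rose by 4.96 ± 0.09, UBE2G1, a ubiquitin-conjugating enzyme that works with that ligase, by 3.73 ± 0.13, and CAND1, which exchanges cullin receptors, by 3.05 ± 0.21. ILF2, a double-stranded RNA binding protein, rose by 3.91 ± 0.15, and TSC2 and TSC1, which restrain mTORC1, by 3.91 ± 0.23 and 3.65 ± 0.27. RPS6KB1, the S6 kinase downstream of mTORC1, fell (−3.21 ± 0.22), though the alpha-RRA ranking did not call it (adjusted p 5.96e-19 to 0.0677 over its alternatives), and USP24, a deubiquitinase, fell (−3.66 ± 0.29). The lowest named gene, SSU72, a phosphatase of RNA polymerase II, stood at −5.09 ± 0.65 with 2 guides; its call (0.0404) was lost without D replicate 1 (0.159), 2 (0.237) or 3 (0.172) and in the alpha-RRA ranking (0.572).

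Of 10 COP9 signalosome genes 8 rose (fry, adjusted p = 0.000105), GPS1 by 3.47 ± 0.20, COPS8 by 3.27 ± 0.13 and COPS4 by 2.90 ± 0.18; COPS5, the catalytic subunit, stood at 0.95 ± 0.40. Of the 8, COPS8 alone kept its call in every alternative run. The alpha-RRA ranking did not call GPS1 (adjusted p 2.85e-43 to 0.0707 over its alternatives), COPS2 (highest 0.0795), COPS3 (0.0548), COPS4 (0.339), COPS6 (0.753), COPS7A (0.0920) or COPS7B (0.189). COPS7A (0.0670, 0.0586 and 0.0508) and COPS7B (0.106, 0.134 and 0.104) were also not called without D replicates 1, 2 and 3. Of 10 neddylation and cullin exchange genes 5 rose, 6 adjusted over the list alone (fry, adjusted p = 0.000403). Among them NAE1 of the NEDD8-activating enzyme rose by 1.91 ± 0.18 and UBA3, its partner, by 3.06 ± 0.22 with 1 guide, and the alpha-RRA ranking called neither (adjusted p 1.65e-10 to 0.781 and 6.63e-43 to 0.332 over their alternatives). CAND2, a further rise in that list, was called neither by that ranking (0.267) nor under total-count scaling (0.0527) nor without D replicate 1, 2 or 3 (0.204, 0.178 and 0.152). Of 7 enzymes of ubiquitin transfer to cullin ligase substrates 4 rose (fry, adjusted p = 0.000403), of which UBE2G1 alone kept its call in every alternative run. The alpha-RRA ranking did not call UBA1 (0.446), UBE2D2 (0.517) or ARIH1 (0.178), and UBE2D2 was also not called without D replicates 1, 2 and 3 (0.123, 0.0671 and 0.130). Of the 5 CRL4-CRBN members CRBN rose, 3 adjusted over the list alone (fry, adjusted p = 0.00155), while DDB1 stood at 1.22 ± 0.45, CUL4B at 0.54 ± 0.18, CUL4A at 0.22 ± 0.10 and RBX1 at −0.05 ± 0.37. CUL4B passed with DESeq2 (0.0379), in the fit of all groups (0.0302) and scaled on control guides (0.00355), and DDB1 and CUL4A passed under that scaling (0.0169 and 0.0228); over its alternatives DDB1 ran from 0.0169 to 1 in adjusted p.

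VHL rose by 2.55 ± 0.17, and it lies close to CRBN in gene order with 37 genes between them. Of the 53 measured genes within 50 of CRBN in gene order 43 rose, VHL included, with a median of 1.51. The share fell with rank in gene order, from 10 of 10 for the nearest on VHL's side (median 1.75) to 22 of 49 for ranks 51 to 100 (0.79) and 6 of 96 for ranks 101 to 200 (0.30); on the other side 1 of 5 rose (0.41). The 4 CRL2-VHL genes held 1 rise (fry, upward, adjusted p = 0.0208), a list call lost without D replicate 2 (0.0696) or 3 (0.0706) or d9A-2 replicate 1 (0.0641) or 2 (0.0651); CUL2 stood at 0.28 ± 0.27. Of 15 genes of apoptosis 2 rose (fry, adjusted p = 0.136), and none of 6 anti-apoptotic genes passed (0.205). Of 39 proteasome genes 2 rose, 3 up and 2 down adjusted over the list alone (fry, adjusted p = 0.205, and 0.0232 without d9A-2 replicate 3). None of 22 V-ATPase genes passed, and the list pointed down (fry, adjusted p = 0.00190) but up when scaled on control guides (0.00412).

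**Figure D5:**
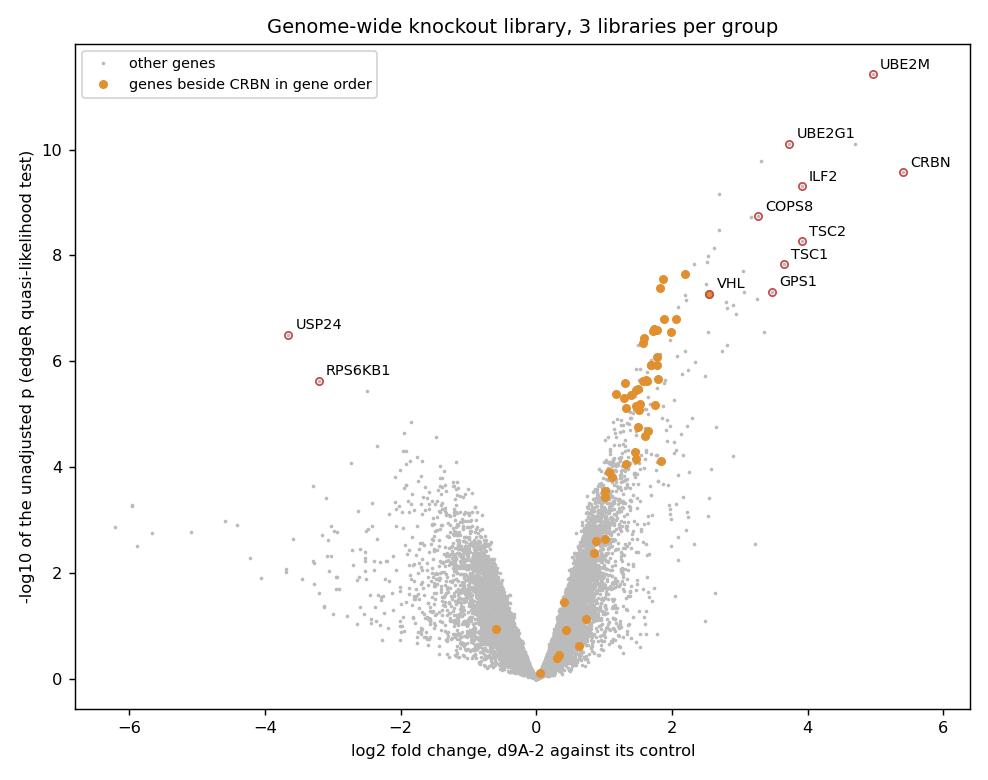
log2 fold change of each gene under d9A-2 against its control (x axis) and −log10 of the unadjusted p of the edgeR quasi-likelihood test (y axis), 3 libraries per group; each point is a gene, and orange marks genes beside CRBN in gene order. CRBN stood at 5.40, and 43 of the 53 measured genes within 50 of it rose.

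In all, 685 of 18046 genes rose under d9A-2 and 192 fell, and guides backed 537 and 100. Scaling decided much of this: total counts gave 422 and 349 with the median of all genes at −0.10, and control guides gave 5337 and 122 with the median at 0.49. The count was 159, 163 and 167 without D replicates 1, 2 and 3, and 1615, 1772 and 1942 without d9A-2 replicates 1, 2 and 3. DESeq2 called 2309, a fit of all 3 groups 2762 and the alpha-RRA ranking 81. From the Input to D, 1083 of 18049 genes rose and 2302 fell, led by PTPMT1, a mitochondrial phosphatase, at −4.41 ± 0.18, with 43 of 66 cytosolic ribosomal protein genes falling (fry, adjusted p = 4.77e-06). MYL6, MYH9 and ROCK2, which act in actomyosin contraction, rose by 0.95 ± 0.10, 0.88 and 0.88, though the alpha-RRA ranking did not call ROCK2 (adjusted p 1.98e-14 to 0.106 over its alternatives). A fit of all 3 groups called 522 and the alpha-RRA ranking 850. Scaled on control guides 6 rose and 14835 fell, with the median at −0.44.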

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

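The tests of genes beside VHL, of the gene pair beside CUL2, of cell divisions and of the 3-day SIM1 replicate 3 were chosen only after the results were seen; the tests of genes beside CRBN, of sequencing depth and of other splits of the libraries were fixed before.

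The effect of MZ1 differed between 9 and 3 days for 38 genes by the edgeR contrast of 4 groups. Of 100 splits of the libraries, the real one included, 3 gave as many, and the highest other split gave 54. For DAT551 it differed for 37 genes, with 5 of 100 splits giving as many and a highest other of 76, and for SIM1 for 12 genes, with 5 of 100 and a highest other of 52. None of these shares decides whether chance can be excluded. The splits shuffled compound and DMSO labels within each arm, which removes the compound effect itself and does not test equal effects in both arms. The other splits that gave as many kept or wholly exchanged the labels of the 9-day arm and so still held a compound effect. The 94 that mixed those labels gave at most 1 call for MZ1, 1 for DAT551 and 0 by edgeR for SIM1. The effect of MZ1 differed with doxycycline for 154 cDNAs and that of YM155 for 73. In each, 2 of 100 splits gave as many, which does not decide for the same reason, and the highest other splits gave 183 and 87. In all 5 the highest other split exchanged compound and DMSO in one arm, which adds the effects of both arms where the contrast subtracts them, and so points to the structure of the compared groups.

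The remaining comparisons, except DMSO against Input at 3 days, whose 2 Input libraries were too few to be split, set 3 libraries against 3, and their 10 splits cannot give a share under 0.1. By edgeR the highest other split gave 0 calls in each, both among splits that parted as many replicate pairs and among the rest, and 1 of the 10 splits, the real one, gave its own count. Against DMSO at 3 days the real values were 48 for MZ1, 31 for DAT551 and 9 for SIM1, and at 9 days 47, 61 and 34, with 32 for YM155. Between compounds they were 7, 4 and 4 at 3 days and 6, 15 and 22 at 9 days, in the order MZ1 against DAT551, MZ1 against SIM1 and DAT551 against SIM1. In the overexpression library they were 220 and 15 for MZ1 with and without doxycycline, 102 and 16 for YM155, and 155 for doxycycline alone. In the genome-wide library they were 877 for d9A-2 and 3385 for D against Input.

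Some genes beside a ligase gene rose under these compounds. Under d9A-2 the 53 measured genes within 50 of CRBN had a median above 100% of 10000 random lists of that size, though 1 of the 5 on one side of CRBN rose, and 71 of the 685 rising genes (10.4%) lay within 200 genes of it. At 9 days the 5 library genes beside VHL had a median of 0.48 under MZ1 (CRBN at −0.18 and SLC6A6 at −0.02 did not rise), 0.77 under DAT551, 0.22 under SIM1 (ATP2B2 did not pass, with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.291) and 0.03 under YM155, and the pair around CUL2 had a mean of at least 1.44 under MZ1, DAT551 and SIM1, carried by SLC9B1P3; both sets were picked after their rises were seen, so they restate them. Fewer cell divisions under the drug, which would raise knockouts that slow growth, are argued against for the genes that rose beside CRBN (median 0.10 ± 0.28, SD, from Input to D) and VHL (−0.042 from Input to DMSO), but stay open for the pair around CUL2 (mean −0.71), since SLC9B1P3 fell (−1.58) and SLC39A12 did not (0.15). A candidate explanation, for which the genes beside CRBN gave the one test fixed beforehand, is that Cas9 breaks at a target removed the neighbouring ligase gene along with it in some cells; no group of the design tests it, and no biological role of the neighbours was tested.

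With doxycycline, 220 of 449 cDNAs changed under MZ1, GFP among them. Unequal depth is argued against, since the libraries thinned to a common total of 325374 counts gave 217 calls. Fewer cell divisions under MZ1 would relieve cDNAs that slow growth and need a clearly negative r with the doxycycline effect. Across 447 cDNAs r was 0.199 with that effect in the YM155 libraries, but these also carry YM155's own selection, so this r cannot decide. With that in DMSO r was −0.047, although the shared DMSO libraries lower it. This argues against fewer divisions as the main source of the changes across the set. MZ1's own selection also weakens this r, so a smaller part of the changes from fewer divisions stays open. The explanation stays open for single cDNAs too. NIPA1, SPNS2 and SLC1A5, the highest named rises with doxycycline in DMSO, fell under MZ1, though the shared DMSO libraries push them that way. A response of the cells to the expressed proteins stays open and untested.

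The 3-day SIM1 replicate 3 held more ABC and P-type ATPase guides than any other library of that screen. Carry-over of the whole library from before culture is argued against, because ABC guides took 9.01% of its counts, above the Input (6.54% to 6.73%), although its essential control genes rose too, by a median of 1.64. Survival of cells that lack these genes is argued against, because guides of their pseudogenes, whose loss should do nothing, also lay 0.46 above those of SLC pseudogenes (18 against 455 guides). Carry-over from a pool rich in these guides stays open: ABC and P-type ATPase genes lay 0.54 and 0.61 above SLC genes in the ratio to the other SIM1 libraries, but this restates the excess and cannot decide. The labels name no such pool, and no biological explanation beyond survival was tested.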

How the results depend on the processing

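The alternative that left out the 3-day SIM1 replicate 3 with the replicate block was chosen only after the data were seen. Counts of calls stayed within 1.5 times under 211 alternatives, rose beyond it under 40 and fell beyond it under 55. Named genes kept direction and side of the threshold under 7851 alternatives, lost the call under 607, gained it under 41 and reversed under 5, and lists did so under 955, 247, 2 and 17. The filter on low counts changed no count beyond 1.5 times and no call of a named gene or list. Most lost calls came from leaving out 1 library (401 of named genes, 181 of lists) and from one fit of all groups (86 of named genes), and the cause was not tested for any change below. In simulated data for d9A-2, with a median of 360 counts per guide, 1.49% of changes of 0.5 were recovered; depth, the spread between dishes and the number of genes were not separated.

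With DESeq2 the counts were 52 and 92 for DAT551 at 3 and 9 days, 46 for SIM1 at 3 days, 53 for YM155, 23 and 27 for MZ1 and DAT551 against SIM1 at 3 days, 41 and 28 for MZ1 and YM155 without doxycycline, and 2309 for d9A-2. One fit of all groups gave 6, 5 and 19 for MZ1, DAT551 and SIM1 at 3 days, 23, 20 and 19 at 9 days, 76 for YM155, 2 and 25 for MZ1 and YM155 without doxycycline, 95 for doxycycline alone, 2762 for d9A-2 and 522 for D against Input. Total counts gave 604 for YM155 at 9 days. The alpha-RRA ranking gave 37 for SIM1 at 3 days, 38 for DAT551 at 9 days, 44 for DMSO against Input, 81 for d9A-2 and 850 for D against Input. Control guides gave 16 for SIM1 at 3 days, 5459 for d9A-2 and 14841 for D against Input.

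The replicate block gave 99, 74 and 5 for MZ1, DAT551 and SIM1 at 3 days, 25 for MZ1 against DAT551 and, by edgeR, 0 for MZ1 against SIM1 at 3 days (42 genes at an unadjusted p under 0.05, 23 calls by DESeq2), and 20, 33 and 56 between these compounds at 9 days. Where the numbers did not pair the libraries, it gave 0 for DAT551 against SIM1 at 3 days (49 unadjusted, 27 by DESeq2) and 1 and 7 for MZ1 and YM155 without doxycycline. Across all comparisons the block lost the call of 42 named genes and 44 lists and gained it for 6 genes, and it changed no other call among the named genes and lists. Without the 3-day SIM1 replicate 3 and with the block, 93 genes passed for SIM1, 54 and 66 for MZ1 and DAT551 against SIM1.

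Reversed under that same alternative were ABCB1 (−0.15 for SIM1, 0.16 for DAT551 against SIM1) and ABCC5 (0.095). Total counts turned the YM155 lists of ABC multidrug exporters (fry, adjusted p = 0.000319), zinc transporters (0.000746), mitochondrial carriers (0.00105) and the SLC35 family (0.00234). Control guides turned the ABCA to ABCG families for DAT551 at 9 days (0.982), amino acid transporters (0.0414), SLC9A exchangers (0.102) and cutting controls (0.0088) for DMSO against Input, essential transporters (0.0852), mitochondrial carriers (0.00141) and V-ATPase (0.00412) for d9A-2, and organic ion uptake for D against Input (0.000104). The cutting controls were scaled there on their own guides, so their turn decides nothing.

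With each library left out in turn, the lowest and highest counts were 2 and 73 for SIM1 at 3 days, 38 and 68 for DAT551 and 17 and 60 for YM155 at 9 days, and 174 and 557 for DMSO against Input. There 1 Input library stood alone and was assumed to vary like the other groups. Between compounds they were 3 and 9 (MZ1 against DAT551), 2 and 39 (MZ1 against SIM1) and 0 and 43 (DAT551 against SIM1) at 3 days, and 3 and 4 (MZ1 against DAT551) and 14 and 25 (DAT551 against SIM1) at 9 days. The 0 was edgeR's without any DAT551 replicate or SIM1 replicate 2, with 29 to 50 genes at an unadjusted p under 0.05 and 23 to 46 calls by DESeq2. They were 10 and 22 for the change of the SIM1 effect, 2 and 22 for MZ1 and 0 and 38 for YM155 without doxycycline (for the 0 by edgeR, 70 unadjusted and 12 by DESeq2), and 159 and 1942 for d9A-2. ABCB1 ran from −0.16 to 0.20 for SIM1 at 3 days and from −0.22 to 0.14 for DAT551 against SIM1, reversed without SIM1 replicate 3. So did the SIM1 lists of ABC multidrug exporters (fry, adjusted p 0.0105 to 0.847) and essential transporters (0.00713 to 0.847). Mitochondrial carriers under YM155 (0.0147 to 0.394) reversed without YM155 replicate 1, and zinc transporters from Input to DMSO (0.0195 to 0.0995) without either Input library.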

Other observations

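SLC35F2, the importer gene of YM155, also differed between the 3-day and the 9-day screen without that drug. Its guides held 3884 ± 708 CPM in DMSO at 9 days against 1752 ± 37.9 at 3 days (SD, n = 3), in separate screens. Under MZ1, DAT551 and SIM1 they held 4362, 3661 and 5054 CPM at 9 days against 1710, 1681 and 1673 at 3 days. The 9-day screen also held the YM155 libraries, at 705296 CPM. Time and screen cannot be told apart here, and no cause was tested.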
